A study of Oryza sativa with 6 samples.

How the data were processed

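Total RNA from 1 mm root tips of rice cultivar IR64 was labelled with Cy3 and hybridised to 6 one-colour Agilent arrays of 60-base probes, 2 each for control, mechanical stress and salinity. Per the file headers, the deposited array files hold intensity values from Agilent Feature Extraction 11.5.1.1, in which the processed signal was background-subtracted and spatially detrended within an array and low spots carried surrogate values, with no scaling between arrays. The authors also deposited a table in log2 units, which on comparison matched the log2 processed signal minus a constant per array that set its 75th percentile to 0, within 0.01 log2 units for at least 99.8% of the 59803 probes that could be matched of 59805. The probe coordinates are those of the IRGSP5 build named in the file headers. Of the genes tested, 474 had a probe placed on another chromosome than their locus and 7236 had one without coordinates. The reference table matched 0 loci to a symbol, so names come from the descriptions in the array files, and 122 loci had a symbol there. Some descriptions name only a similar protein, so a name taken from them need not be the gene's own.

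The processed signal was taken to log2, the 75th percentile of each array was subtracted, and spots of the same probe were averaged, which gave 59805 probes. Left out were 88 probes flagged as outliers on an array, 1021 that named several loci and 484 that named none. A probe was kept when it was well above background, by the flag in the files, on both arrays of at least 1 group (44551 probes). Each gene was represented by its brightest kept probe, which gave 29920 tested genes of 41991 loci on the array, 15233 of them with a functional description. Where a gene had several kept probes, they were compared: of 1314 such genes called in salinity, 3 had a probe called the other way and 56 had any probe of opposite sign. No spot was saturated, and the median local background of an array was between 28 and 32 intensity units, against a 75th percentile of processed signal of 2524 or more. The number of arrays limits the precision.

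Groups were taken from the sample labels. Mechanical stress against control, salinity against control and salinity against mechanical stress were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 6 arrays, two-sided), with Benjamini-Hochberg adjustment over the 29920 genes and a threshold of 0.05. Gene lists, 32 in all, for wall, hormone, stress, transport, growth and other-tissue genes, were tested with camera (preset correlation 0.01, lists of at least 5 measured genes), again adjusted over the lists of a comparison. Counts of passing members are given over all genes and adjusted over the list alone. Camera was also run with a correlation estimated per list, and fry, which tests whether a set's genes move on balance in one direction. Overlap of the stresses was set against 100 simulations of unchanged groups that shared the controls, with each gene drawn independently. Shares among selected genes were set against 100 further simulations with no group changed and 100 with only salinity changed, in each of which as many genes were picked by p as were called, added after the data were seen. Another 100 with only salinity changed used the threshold itself. The share of genes whose groups did not overlap was 63.3% for mechanical stress against control, 70.2% for salinity against control and 47.3% for salinity against mechanical stress, where chance gives 33.3%.

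The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule took, for each stress against control, the 10 largest rises and 10 largest falls among called genes with a description, no overlap between the groups and signal above background in the brighter group, 5 and 5 for salinity against mechanical stress, and up to 4 measured members of each list with the smallest p, while members of the lists given by identifier (transport, abscisic acid and root regulator genes) may be named in any comparison. Where no gene was called, the genes with the smallest p in each direction were taken. The text gives the values of part of these genes. A few more genes were named after their values were seen and are marked so. Tested on simulated data, in which 200 genes were changed, the fit called 74.6% of genes changed by 2 log2 units and 8.96% of those changed by 1 in mechanical stress against control, and when 7480 genes were changed, 75.9% of those changed by 1. These simulations drew each gene independently around the spread estimated by the fit, so the rates may be too high for the data. Drawn with salinity at its measured means, such simulations called 9923 genes on average, where the data gave 5050.

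Alternatives were normexp background correction with an offset of 50, quantile normalization, array medians set to 0, the deposited log2 table, no background filter, signal above background on all 6 arrays, the mean of a gene's kept probes, every probe tested, a replicate block, an intensity trend or robust estimation of the variance, only the groups compared, a minimum of 2-fold and each array left out in turn. An adjusted p under 0.10, list medians with array medians set to 0, removal of list members caught by another meaning of their names and removal of list members with a probe on another chromosome were added after the data were seen. Calculations used data.table version 1.17.8 and figures matplotlib 3.10.9.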

Results

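Gene expression was measured in 1 mm root tips of rice (Oryza sativa, cultivar IR64) with one-colour oligonucleotide arrays carrying 62976 spots. Seedlings were grown in tubes with a lower and an upper layer of gelled medium, and the upper layer held the control medium in every group. The lower layer was control medium set with 1% phytagel, a gelling agent, in the control group. It was a stiffer gel with 2.5% phytagel in the mechanical stress group, and 1% phytagel with 400 mM NaCl in the salinity group. Each of the 3 groups had 2 arrays, and this number limits the precision of every value below. Between 71.4% and 74.3% of the 61657 non-control spots of an array lay well above background, and the 75th percentile of the processed signal lay between 2524 and 2998. Arrays of the same group correlated across genes at 0.992 in control, 0.985 in salinity and 0.982 in mechanical stress, where genes are not independent replicates. The first principal component held 59.1% of the variance. It placed the control arrays at -84.8 and -93.4, the mechanical arrays at 11.8 and -21.3 and the salinity arrays at 78.5 and 109. All arrays shared 1 slide and 1 scan, with the 2 control arrays in one slide column and the 4 stress arrays in the other, so slide column and stress against control cannot be told apart. The mechanical and control arrays lay in slide rows 1 and 2 and the salinity arrays in rows 3 and 4. Slide row and salinity against either other group therefore cannot be told apart, which includes salinity against mechanical stress. Signals are given as log2 units relative to the 75th percentile of the array, group values as mean ± SD (n = 2 arrays) and log2 fold changes as estimate ± SE. A gene that lay below background on both arrays of a group has its fold given as a bound, "at least", against the lowest signal that counted as above background.

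The first comparison asked how root tips that met saline medium differed from control tips. Relative to all genes, salinity tips carried more transcript of photosystem proteins, of pathogenesis-related proteins and chitinases, and of WRKY and NAC transcription factors, and less of ribosomal proteins, histones and the machinery of the cell cycle. With late embryogenesis, abscisic acid, glutathione S-transferase, seed and peroxidase genes, 12 lists passed camera's test with a preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.208). The photosystem I subunit VI precursor Os05g0560000 was at least 27.3-fold higher, and the ethylene-forming ACC oxidase Os02g0771600 rose from -6.93 ± 0.03 to -0.55 ± 0.81, or 83.0-fold. The sodium transporter OsHKT1;1 (Os04g0607500) fell from -1.15 ± 0.10 to -2.51 ± 0.08, a change of -1.36 ± 0.17 (adjusted p = 0.0150). The root potassium channel OsAKT1 (Os01g0648000) fell 3.34-fold, from 0.75 ± 0.26 to -0.99 ± 0.24. Of 29920 genes tested, 3037 rose and 2013 fell in salinity against control (limma, adjusted p under 0.05), and 2545 of the rises and 1073 of the falls reached 2-fold.

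Among the named genes, the steepest rise was in a gene similar to non-specific lipid-transfer protein 2, Os05g0550600, whose probe lay at 27462234 to 27462293 of chromosome 5 (IRGSP5). It went from -6.41 ± 1.28 in control, where 1 of 2 arrays was above background, to 2.22 ± 0.62 in salinity, a log2 fold change of 8.64 ± 0.72 (398-fold, adjusted p = 0.00854). The cationic peroxidase isozyme gene Os07g0677600 rose 396-fold, again with 1 of 2 control arrays above background. The senescence-associated gene homologue Os03g0347500 (SAG29) rose by 8.46 ± 1.74 and the RIR1b homologue Os10g0569800 by 8.39 ± 1.52, each with 1 of 2 control arrays above background. Genes that were dim in control included the photosystem I subunit O gene Os04g0414700, at least 87.2-fold higher, and the cytochrome P450 gene Os02g0569900, at least 61.2-fold higher. The proline-rich protein gene Os05g0226900 was at least 62.2-fold higher. Among the falls, the papain-type cysteine protease gene Os01g0347600 (similar to ervatamin B; chromosome 1, 13986341 to 13986400) went from 4.02 ± 0.19 to -1.20 ± 0.37, or 37.0-fold lower (adjusted p = 0.00642). A glucanase gene similar to isoenzyme GII, Os01g0941200, was at least 37.5-fold lower and the papain-type protease gene Os01g0217200 at least 29.4-fold lower. A dirigent-like gene, Os11g0179700, fell 26.4-fold, and the gene of the tonoplast aquaporin TIP4-3, Os01g0232000, fell 32.1-fold with 1 of 2 salinity arrays above background.

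Of 42 photosynthesis genes, a list included as a marker of green or light-exposed tissue, 22 rose and 1 fell in salinity (26 and 1 adjusted over the list alone). Their median log2 fold change was 1.49, or 1.45 with dim genes at their bound (camera adjusted p = 1.92e-10, and adjusted p = 0.208 with an estimated correlation). The oxygen-evolving complex gene Os01g0501800 rose 20.4-fold, from -4.48 ± 0.08 to -0.13 ± 0.53, and the 23 kDa photosystem II polypeptide gene Os07g0141400 rose 27.2-fold.

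Of 100 chitinase, glucanase and pathogenesis-related genes, 26 rose and 3 fell (34 and 6 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.000487, and adjusted p = 0.208 with an estimated correlation). The PR-10a gene Os12g0555300 rose 11.3-fold, from 0.83 ± 0.19 to 4.33 ± 0.06, and the class III chitinase gene Os08g0518800 rose 14.3-fold, while the thaumatin gene Os11g0703000 fell 8.04-fold. Of 66 WRKY genes, 16 rose and 4 fell (25 and 4 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00645, and adjusted p = 0.786 with an estimated correlation). A gene described as similar to WRKY23 (Os03g0758000) rose 10.9-fold, from -3.98 ± 0.34 to -0.53 ± 0.23. Of 43 NAC genes, 12 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.00109, and adjusted p = 0.756 with an estimated correlation). The NAC member that fell, Os08g0115800, did so 2.89-fold. Of 51 glutathione S-transferase genes, which act in detoxification, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00434, and adjusted p = 0.738 with an estimated correlation). Genes described as similar to glutathione S-transferase 29 (Os01g0950300) and glutathione S-transferase I (Os01g0374000) rose 4.36-fold and 12.8-fold. Setting each array's median to 0 moved the median of all genes from -0.07 to -0.42 and put the medians of the WRKY (-0.06), glutathione S-transferase (-0.02), chitinase (-0.01) and seed (-0.03) lists just below 0, all above the median of all genes.

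Of 23 late embryogenesis abundant (LEA) proteins and dehydrins, which protect drying cells, 3 rose and none fell (9 and 1 adjusted over the list alone). Their median was 2.77, or 1.55 with dim genes at their bound (camera adjusted p = 0.00124, and adjusted p = 0.786 with an estimated correlation). The dehydrin gene Rab25 (Os01g0702500) rose 15.5-fold, from -6.40 ± 0.45 to -2.44 ± 0.67, and the group 1 LEA gene Os08g0327700 was at least 16.4-fold higher. The 18 measured abscisic acid and osmotic stress markers had a median of 0.76 (camera adjusted p = 0.0245, and adjusted p = 0.738 with an estimated correlation). They include the RAB16 dehydrins, so this list and the LEA list can share genes and are not independent. None of these markers rose, 2 fell, and 0 passed adjusted over the list alone. Those that fell were OsNCED3 (Os03g0645900), of abscisic acid synthesis, which fell 2.13-fold, and the trehalose phosphatase gene OsTPP1 (Os02g0661100), which fell 2.94-fold. The dehydrin RAB16D (Os11g0453900) went from -5.27 ± 0.72 to 0.75 ± 1.54 (adjusted p = 0.0666), and SalT (Os01g0348900), a salt-induced lectin, had a log2 fold change of 2.82 ± 0.86 (adjusted p = 0.0774). Of 31 seed storage and reserve genes, a list included as a marker of seed tissue, 7 rose and 2 fell (12 and 3 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0257, and adjusted p = 0.738 with an estimated correlation). The amylase 3D gene Os08g0473900 was at least 2.66-fold higher and the glutelin gene Os01g0762500 at least 2.04-fold higher. With 9 members caught by another meaning of their names taken out, the seed list had a median of 0.56 and was no longer called (adjusted p = 0.119). The abscisic acid call was also lost without salinity replicate 1 (median 0.67), salinity replicate 2 (0.51) or control replicate 2 (0.54), and the seed call without control replicate 2 (0.41) and with signal required above background on all arrays (0.24).

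Of 144 cytosolic ribosomal protein genes, none rose and 23 fell (1 and 105 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 2.61e-16, and adjusted p = 0.786 with an estimated correlation). The 40S ribosomal protein S10-1 gene Os01g0962600 fell 2.05-fold, from 4.97 ± 0.06 to 3.93 ± 0.17. Of 38 core histone genes, 9 fell and none rose (26 and 0 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 3.01e-07, and adjusted p = 0.786 with an estimated correlation). The histone H3 gene Os04g0419600 fell 1.75-fold. Of 81 cyclins, kinesins and DNA replication factors, 9 fell and 3 rose (5 and 3 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.00109, and adjusted p = 0.756 with an estimated correlation). The DNA polymerase alpha subunit B gene Os05g0160800 fell 1.94-fold. One of the members that rose was the cyclin-dependent kinase inhibitor 7 gene Os10g0471700, whose product restrains cell division, at 1.79-fold. Random lists matched on mean expression typically had medians below 0 too, at -0.42 for ribosomal proteins, -0.35 for histones and -0.13 for cell-cycle genes.

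Cell wall genes moved in both directions. Of 62 class III peroxidases, 11 rose and 19 fell (13 and 29 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.0326, and adjusted p = 0.786 with an estimated correlation). The call was lost without salinity replicate 2, where the median was -0.54, with quantile normalization (-0.56) and with array medians set to 0 (-0.99). A gene described as similar to peroxidase 1 (Os03g0368300) fell 4.31-fold and the peroxidase gene Os12g0112000 rose 13.1-fold. The 20 other lists had medians between -0.71 and 0.18 and did not pass camera's test, although single members did. Among 41 expansins, which loosen walls, 7 rose and 6 fell (8 and 8 adjusted over the list alone), and 4 of 15 xyloglucan endotransglucosylase/hydrolases fell (8 adjusted over the list alone, beside 2 that rose). Expansin-B7 (Os03g0102700) rose 3.36-fold and a beta-expansin 5 precursor gene, Os04g0552200, fell 9.25-fold. Of 55 lignin and phenylpropanoid genes, 8 rose and 3 fell (9 and 5 adjusted over the list alone), with a median of -0.20 and a mean of 0.22, which differ in sign. The laccase gene Os03g0273200, for lignin polymerisation, was at least 15.1-fold higher.

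Ion transport, iron and calcium genes added single changes. Of 10 sodium and potassium transport genes, 1 rose and 3 fell (3 and 4 adjusted over the list alone). The calcium sensor gene OsCBL4 (Os05g0534400) rose 2.76-fold, and the vacuolar sodium exchanger gene OsNHX2 (Os05g0148600) fell 1.70-fold beside the falls of OsHKT1;1 and OsAKT1. OsHKT2;1 (Os06g0701700) had a log2 fold change of -2.36 ± 0.59 (adjusted p = 0.0542) and OsSOS1 (Os12g0641100) one of 0.60 ± 0.16 (adjusted p = 0.0605). Nicotianamine synthase 3 (Os07g0689600), which makes a metal chelator, rose 3.83-fold, and 3 of 11 iron uptake genes rose (4 adjusted over the list alone, beside 1 that fell). The calcium- and calmodulin-dependent kinase gene Os05g0489900 rose 4.17-fold, within a list of 105 calcium sensors of which 15 rose and 15 fell. The WOX11 gene (Os07g0684900), a regulator of crown root initiation, rose 3.35-fold, and a non-symbiotic haemoglobin gene, Hb4 (Os03g0234100), fell 9.81-fold.

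Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between samples that may be technical replicates. The count of 5050 genes was 478 without control replicate 1, 84 without control replicate 2 and 621 without salinity replicate 2, and of the 102 genes followed in this comparison 65, 90 and 60 lost their call without these arrays in turn (20 without salinity replicate 1). It was 11641 with array medians set to 0 (2567 up and 9074 down, 22.1% up against 60.1%), 4830 with quantile normalization (2321 up and 2509 down, 48.1% up), 2037 without the background filter and 7608 with an intensity trend in the variance.

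**Figure D1:**
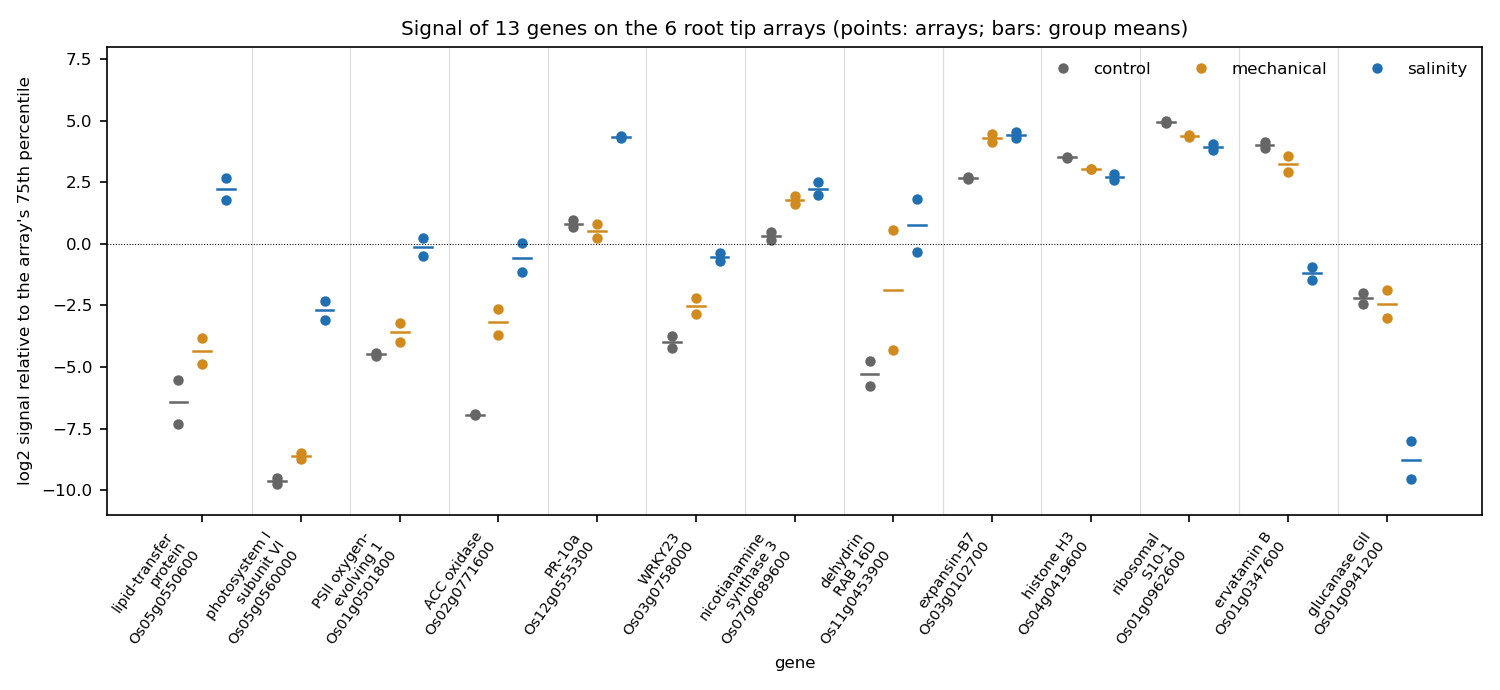
Signal of 13 named genes on each array (points; y axis, log2 units relative to the 75th percentile of the array) with group means as bars, for control, mechanical stress and salinity, 2 arrays each. The mechanical arrays lie between the other groups for the ACC oxidase gene and far apart from each other for RAB16D.

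**Figure D2:**
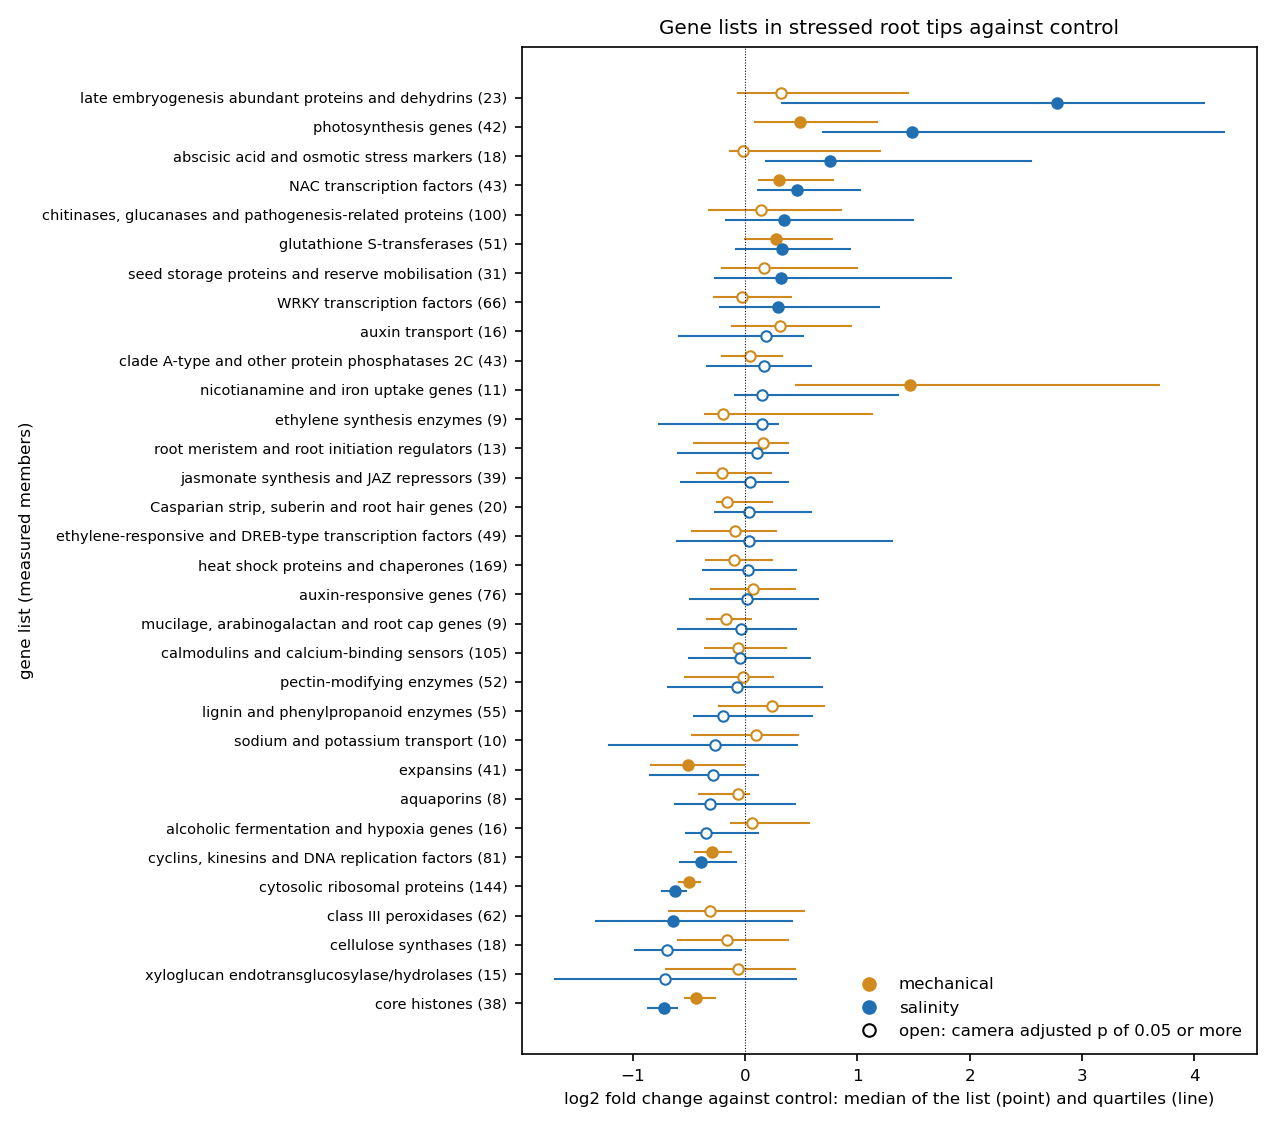
Median log2 fold change (points) and quartiles (lines) of each gene list in mechanical stress and in salinity against control, with open points for lists whose camera adjusted p was 0.05 or more. Photosynthesis genes reached 1.49 in salinity, and ribosomal proteins and histones were below 0 in both stresses.

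The second comparison asked how root tips that met a stiffer gel differed from control tips. Relative to all genes, iron acquisition, glutathione S-transferase, NAC and photosynthesis genes were shifted upward as groups, and expansins, histones, cell-cycle and ribosomal protein genes downward. These 8 lists passed camera's test with a preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.560). The iron-phytosiderophore transporter gene Os04g0542200 was at 0.04 ± 0.37 in mechanical stress and -2.01 ± 0.31 in control, and nicotianamine synthase 3 (Os07g0689600) at 1.78 ± 0.22 and 0.31 ± 0.24. The ethylene-forming ACC oxidase Os02g0771600 was at -3.18 ± 0.74 and -6.93 ± 0.03. No single gene passed the threshold: limma called 0 of 29920 genes, while 7312 had an unadjusted p under 0.05 (3887 higher and 3425 lower), and the smallest adjusted p was 0.0568. Fits with an intensity trend in the variance or with robust variance estimation also called 0 genes.

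The values of named genes below are therefore given without a call. The serine carboxypeptidase gene Os03g0386800 (Peptidase S10 family) had a log2 fold change of 2.32 ± 0.13 (adjusted p = 0.0771), and the terpenoid synthase gene Os02g0121700, dim in control, a fold of at least 3.59 (adjusted p = 0.0792). On the lower side, the jasmonate-pathway Tify gene Os03g0180800 was at -1.88 ± 0.22 and an NB-ARC resistance-type gene, Os11g0606400, at -1.44 ± 0.17 (both adjusted p = 0.0867). Among cell wall genes, the laccase gene Os03g0273200, dim in control, had a fold of at least 8.11 (adjusted p = 0.0792), and the xyloglucan endotransglucosylase gene Os04g0604900 a log2 fold change of 3.60 ± 0.67 (adjusted p = 0.107). A polygalacturonase beta chain gene, Os10g0409400, was at 3.69 ± 0.56 (adjusted p = 0.0953). A chitinase gene, Os05g0247100, was at 6.76 ± 0.14 in mechanical stress and 5.10 ± 0.08 in control (adjusted p = 0.0867). OsHKT1;1 (Os04g0607500) had a log2 fold change of -1.17 ± 0.17 (adjusted p = 0.0953). RAB16D (Os11g0453900) was at -1.87 ± 3.43 in mechanical stress, an SD larger than that of any other group for this gene, and RAB21 (Os11g0454300) had a log2 fold change of 1.67 ± 1.99 that was -1.20 without mechanical replicate 2.

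All 11 nicotianamine and iron uptake genes, which serve iron capture from the medium, were higher, with a median of 1.47 (camera adjusted p = 2.72e-05, and adjusted p = 0.560 with an estimated correlation). None passed over all genes, and 8 did adjusted over the list alone. One of the 11, Os08g0466600, had a probe placed on another chromosome than its locus, so its identity is uncertain, and without it the median was 1.05 (camera adjusted p = 0.000173). The nicotianamine aminotransferase gene OsNAAT1 (Os02g0306401), whose probe had no coordinates, was at 0.30 ± 0.74 against -4.29 ± 1.49. The 51 glutathione S-transferases had a median of 0.28 (camera adjusted p = 0.000624, and adjusted p = 0.560 with an estimated correlation), with 5 higher adjusted over the list alone. The 43 NAC genes had a median of 0.30 (camera adjusted p = 0.00258, and adjusted p = 0.560 with an estimated correlation), with 0 adjusted over the list alone. The 42 photosynthesis genes had a median of 0.48 (camera adjusted p = 0.00150, and adjusted p = 0.560 with an estimated correlation), with 1 higher adjusted over the list alone.

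Of 144 ribosomal protein genes, 143 were lower, with a median of -0.50 (camera adjusted p = 3.32e-19, and adjusted p = 0.723 with an estimated correlation). Of 38 core histones, 34 were lower, with a median of -0.44 (camera adjusted p = 0.000173, and adjusted p = 0.829 with an estimated correlation), and the 81 cell-cycle genes had a median of -0.29 (camera adjusted p = 0.000185, and adjusted p = 0.560 with an estimated correlation). No member of the histone and cell-cycle lists passed, over all genes or adjusted over the list alone. Random lists matched on mean expression typically had medians of -0.22 for ribosomal proteins, -0.20 for histones and -0.11 for cell-cycle genes. The 41 expansins had a median of -0.51 (camera adjusted p = 0.0142, and adjusted p = 0.815 with an estimated correlation), with 6 lower and 2 higher adjusted over the list alone. Among them were Os01g0248900 at -1.06 ± 0.15 and expansin-B7 (Os03g0102700) at 1.64 ± 0.19. The 24 other lists had medians between -0.31 and 0.32 and did not pass, and of the chitinase and pathogenesis-related list 15 were higher and 2 lower adjusted over the list alone.

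Without mechanical replicate 2 the count of called genes was 131, without mechanical replicate 1 it was 14, and without mechanical replicate 1 the expansin (median -0.28) and NAC (0.17) calls were lost, as was the expansin call without control replicate 1 (-0.52), with quantile normalization (-0.48) or with array medians set to 0 (-0.69), and the histone call with quantile normalization (-0.29). Setting array medians to 0 moved the median of all genes from -0.05 to -0.24, and at an adjusted p under 0.10, a threshold chosen after the data were seen, 435 genes were higher and 57 lower.

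The third comparison tested the difference between the stresses directly. Relative to all genes, salinity tips carried more photosystem, WRKY, LEA, abscisic acid, heat shock and pathogenesis-related transcripts than mechanically stressed tips, and less of the iron acquisition, histone and ribosomal protein groups. These 9 lists passed camera's test with a preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.30). The PR-10a gene Os12g0555300 was at 4.33 ± 0.06 in salinity and 0.53 ± 0.39 in mechanical stress, 13.9-fold higher (adjusted p = 0.0148). The potassium channel OsAKT1 (Os01g0648000) was at -0.99 ± 0.24 and 1.28 ± 0.25, 4.82-fold lower in salinity. In all, 382 genes were higher and 275 lower in salinity than in mechanical stress, of 29920 tested (limma, adjusted p under 0.05).

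The cytochrome P450 gene Os02g0569900 was at least 66.5-fold higher in salinity, and the ent-kaurene oxidase gene Os06g0569500, of a diterpenoid pathway, at least 55.1-fold higher. The lipid-transfer gene Os05g0550600 was 94.7-fold higher. The cytochrome P450 gene Os10g0165300 was at -5.10 ± 0.51 in salinity and -0.56 ± 0.51 in mechanical stress, 23.1-fold lower (adjusted p = 0.0184). The papain-type protease genes Os01g0347600 and Os01g0217200 were 22.0-fold and at least 17.3-fold lower, and the dirigent-like gene Os11g0179700 was 19.9-fold lower. Of 39 jasmonate genes, 3 were higher and 2 lower in salinity (4 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.447). They included the Tify gene Os03g0180800, 6.21-fold higher, and the allene oxide synthase gene Os02g0218800, 2.65-fold lower.

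Of 42 photosynthesis genes, 10 were higher and none lower (20 and 1 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 3.18e-10, and adjusted p = 0.30 with an estimated correlation). The photosystem I genes Os04g0414700 and Os05g0560000 were at least 94.8-fold and at least 29.7-fold higher. Of 66 WRKY genes, 8 were higher (12 higher and 1 lower adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.000331, and adjusted p = 0.683 with an estimated correlation). The WRKY gene Os01g0626400 was 6.59-fold higher. Of the 100 chitinase and pathogenesis-related genes, 3 were higher and 1 lower (16 and 4 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.00624, and adjusted p = 0.30 with an estimated correlation). The endochitinase gene Os05g0399400 was 12.6-fold higher, with 1 of 2 mechanical arrays above background. LEA proteins had a median of 1.51 (camera adjusted p = 0.000331) and abscisic acid markers one of 0.66 (camera adjusted p = 0.0145), with no member past the threshold (both adjusted p = 0.683 with an estimated correlation). These lists can share dehydrins and are not independent. Of 169 heat shock proteins and chaperones, 1 was higher, a small class I protein (Os01g0136100, 5.01-fold), and the list's median was 0.08 against -0.02 for all genes, or -0.08 against -0.18 with array medians set to 0 (camera adjusted p = 0.0413, and adjusted p = 0.683 with an estimated correlation).

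On the lower side, iron uptake genes had a median of -0.92 (camera adjusted p = 0.00644, and adjusted p = 0.683 with an estimated correlation), with 8 of 11 lower and 1 higher adjusted over the list alone. Without Os08g0466600, whose probe was placed on another chromosome, the median was -0.75 (camera adjusted p = 0.0170). OsNAAT1 (Os02g0306401) was at -3.90 ± 1.31 in salinity and 0.30 ± 0.74 in mechanical stress (adjusted p = 0.105). Core histones had a median of -0.31 (camera adjusted p = 0.000267, and adjusted p = 0.696 with an estimated correlation), a call lost with quantile normalization (-0.19). Ribosomal proteins had a median of -0.14, which was 0.07 with quantile normalization and 0.03 without salinity replicate 2 (camera adjusted p = 0.0145, and adjusted p = 0.807 with an estimated correlation). Random lists matched on mean expression were not drawn for this comparison. Against control, their medians for ribosomal proteins were -0.42 in salinity and -0.22 in mechanical stress. For histones they were -0.35 and -0.20. Whether the histone and ribosomal falls exceed those of equally bright genes was therefore not tested. The 23 other lists did not pass.

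The count of 657 genes was 385 and 224 without mechanical replicates 1 and 2, 73 and 44 without salinity replicates 1 and 2, 43 without either control replicate, and 102 without the background filter, and of the 34 genes followed here 12 and 19, 24 and 25, and 24 lost their call without these arrays. Calls lost without 1 array were LEA (median 0.37), heat shock (0.04), iron (-1.09) and abscisic acid (0.25) without mechanical replicate 1, WRKY (0.09) and ribosomal (-0.04) without mechanical replicate 2, iron (-0.88) without salinity replicate 1, and heat shock (0.09), histone (-0.09) and abscisic acid (0.39) without salinity replicate 2, while array medians set to 0 gave 318 genes higher and 416 lower (43.3% higher against 58.1%).

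The last comparison asked whether the stresses moved the same genes. With no gene called in mechanical stress, 0 genes were called in both by limma. Across the 29920 genes, the log2 fold changes correlated at 0.681, where 100 simulations of unchanged groups against the same controls gave 0.501 on average (0.475 to 0.523). The covariance was 0.513 against 0.0536 in the simulations. The same sign was seen for 78.6% of genes against 66.6% in the simulations, which exceeds an even share because the controls were shared. The simulations drew each gene independently, with the same spread in all groups, so they hold no shift common to many genes. A shift common to the control arrays or to their slide column would also raise the observed values. The excess over the simulations cannot be told apart from such a shift. Of the 5050 genes called in salinity, 92.1% had the same sign in mechanical stress. The same number of genes picked by p gave 82.6% (81.1 to 83.7) when no group was changed, and 59.2% (57.2 to 61.0) when salinity was set to its measured means and mechanical stress was left unchanged. With genes called by the threshold, simulations of the latter kind called 9923 genes on average (9688 to 10218), of which 58.9% had the same sign. They therefore do not match the data in the number of calls, and they too drew genes independently. The ACC oxidase Os02g0771600, the laccase Os03g0273200, nicotianamine synthase 3 (Os07g0689600) and the kinase Os05g0489900 all rose in salinity and had higher means in mechanical stress. Between them, adjusted p in mechanical stress ran from 0.0792 to 0.102. Without mechanical replicate 2 the overlap was 96 genes and without mechanical replicate 1 it was 7, and at an adjusted p under 0.10 it was 422.

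**Figure D3:**
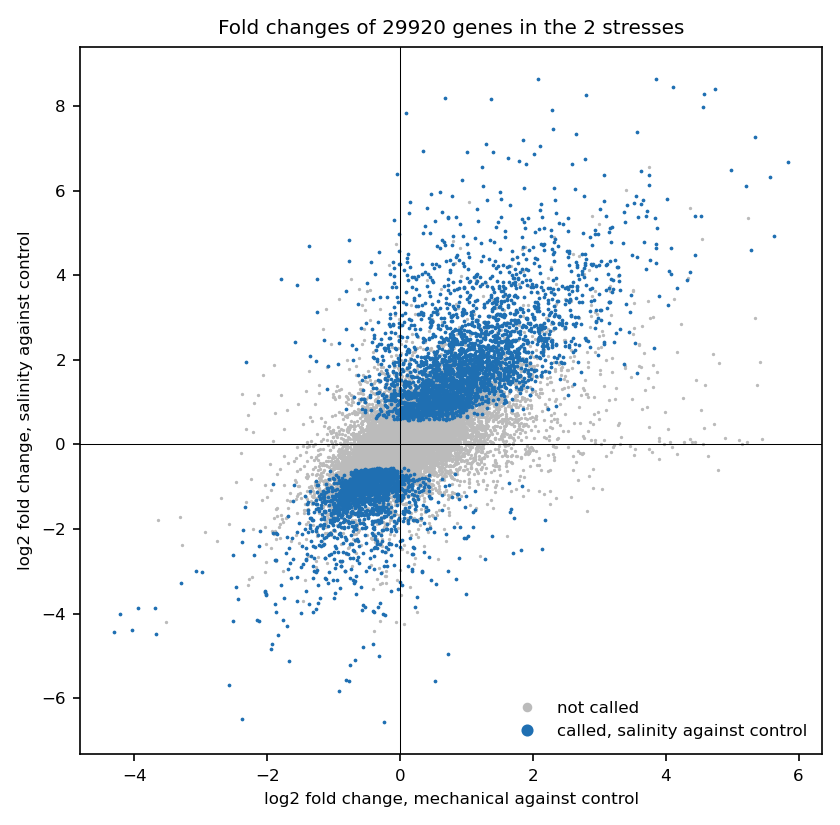
Log2 fold change against control of 29920 genes in mechanical stress (x axis) and salinity (y axis), each point a gene, with genes called in salinity in blue. The same sign was seen in both stresses for 78.6% of the genes, against 66.6% in simulations of unchanged groups with shared controls, and the correlation across genes was 0.681 against 0.501. The simulations drew genes independently, so they leave out shifts common to the control arrays.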

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

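Of the tests in this part, those on scaling of photosynthesis genes, on dividing cells and on both explanations of the RAB16 genes were chosen only after the result was seen.

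Of 791 probes that matched more than 1 gene, 10 were higher and 4 lower in mechanical stress than in control, and 85 were higher and 68 lower in salinity (limma, adjusted over these probes). Of 129 probes that matched no gene locus, 12 were higher and 4 lower in salinity than in control, and in mechanical stress limma called 0, with 16 at an unadjusted p under 0.05 and a smallest adjusted p of 0.138.

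Photosynthesis genes were higher in salinity tips than in control tips, with a median of 1.49 and 22 of 42 called (adjusted p = 0.208 with an estimated correlation). Array scaling or background handling as the whole source is argued against, since the lowest median over normexp, quantile and array-median settings was 0.986, with normexp. Shoot tissue carried into the salinity samples may contribute and stays open: 6 genes taken as leaf markers outside photosynthesis with signal above background in salinity or control (YABBY factors and thionins, 5 of them above background in control) had a median of 0.24 and an upper quartile of 1.09, with 1 rise and 0 falls. The rise was in the thionin gene Os03g0130300, at 0.37 ± 0.02 in control, and the thionin gene Os06g0512700 was at 4.15 ± 0.15 there. Both were well expressed in control root tips, so they do not mark leaf tissue here, and the set cannot decide. The most abundant leaf messages gave no single answer, as the Rubisco small subunit gene Os12g0274700 was at -4.57 ± 0.06 in control and -4.39 ± 0.06 in salinity, while Os12g0292400 had a log2 fold change of 1.35 (adjusted p = 0.0124), Os12g0291100 one of 4.75 (adjusted p = 0.0552) and the activase gene Os11g0707000 one of 3.63 (adjusted p = 0.133), the last 2 with 1 of 2 control arrays above background. A response to salt itself, or light reaching the tips, may also contribute, and neither was tested.

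The histone, ribosomal and cell-cycle lists had medians below 0 in both stresses against control, with 0 members called in mechanical stress and 9, 23 and 9 falls in salinity, and each list's call was lost with an estimated correlation (adjusted p = 0.560 to 0.829). Scaling that depends on expression level is argued against as the whole source, since each list's median lay at or below the percentile 0.04 of 10000 random lists matched on expression, in both stresses. It may account for part, because matched random lists had medians below 0 as well, at -0.42 for ribosomal proteins and -0.35 for histones in salinity, and -0.22 and -0.20 in mechanical stress. A lower share of dividing cells in the tip may contribute and stays open: 20 mature root zone genes had a median of 0.0376 in salinity with an upper quartile of 0.583 and -0.16 in mechanical stress (upper quartile 0.24), 9 root cap genes had medians of -0.04 and -0.17 (upper quartile 0.05 in mechanical stress), and with 7 of 20 and 4 of 9 members higher in mechanical stress the medians below 0 do not decide it there. A lower expression per cell under both stresses stays open and was not tested.

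RAB16 dehydrin genes were higher in mechanical replicate 2 than in mechanical replicate 1. A spot or probe fault is argued against, since both RAB16 probes above background on the 2 mechanical arrays showed it, by 4.86 (RAB16D) and 5.73 (RAB21) log2 units, and the other 2, dim in mechanical replicate 1, differed by at least 1.91 and 4.40. A salinity sample on that array is also argued against. Over all genes, log2 differences of mechanical replicate 2 had an SD of 0.880 and 0.921 from the salinity arrays, 0.720 from each control array and 0.626 from mechanical replicate 1. Mechanical replicate 1 lay nearer to salinity, at 0.855 and 0.871 from the salinity arrays and 0.889 and 0.896 from the control arrays. Over the 5050 salinity-called genes, the median position of mechanical replicate 2 between control (0) and salinity (1) was 0.442, against 0.578 for mechanical replicate 1. This position decides little by itself, because the arrays that define its ends also picked the genes. Such picking gave a mechanical position of 0.499 in simulations with no group changed, but 0.0377 in those with only salinity changed. Picking alone therefore need not account for the observed positions. For RAB16D and RAB21 the salinity arrays differed by 2.18 and 2.76 log2 units and the control arrays by 1.01 and -0.20. Disagreement between the mechanical arrays was not confined to RAB16 genes or to this direction. The SAG29 homologue Os03g0347500 was at -0.24 in mechanical replicate 1 and -5.02 in mechanical replicate 2. No biological explanation was tested, since the design gives none that separates replicates.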

How the results depend on the processing

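The added tests, chosen only after the results were seen, were an adjusted p under 0.10, list medians with array medians set to 0, removal of list members caught by another meaning of their names and removal of list members with a probe on another chromosome. The cause of a change was not tested unless given.

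In mechanical stress against control 0 genes were called under every alternative except an adjusted p under 0.10, which called 492, and some of the left-out arrays (0 to 131). In salinity against control the 5050 genes became 11641 with array medians set to 0, 2037 without the background filter, which raises the number of genes tested, 7866 with every probe tested, 7608 with an intensity trend, 9678 at an adjusted p under 0.10 and 84 to 4626 with 1 array left out; the other settings, apart from the replicate block given below, gave 3618 to 6397. In salinity against mechanical stress the 657 genes became 1032 with normexp, 102 without the filter, 1031 with every probe, 43 with only these groups in the fit, which leaves fewer arrays, 1641 at an adjusted p under 0.10 and 43 to 385 with 1 array left out. Shared calls went from 0 to 422 at an adjusted p under 0.10 and to between 0 and 96 with 1 array left out. The correlation of the stresses, 0.681, was 0.614 without the filter and 0.590 to 0.713 with 1 array left out. Where an array is left out, its group has 1 array, which is assumed to vary like the others.

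With an estimated correlation the 8, 12 and 9 called lists (mechanical stress against control, salinity against control, salinity against mechanical stress) became 0, 0 and 0. With fry they became 0, 4 and 1. With 1 array left out they were 7 to 10, 10 to 12 and 5 to 10. Reversed signs were seen in salinity against control with array medians set to 0 for the median of the glutathione S-transferase (-0.0200), WRKY (-0.0557), chitinase (-0.00616) and seed (-0.0325) lists, because this scaling lowers every salinity value against control. In salinity against mechanical stress they were seen for heat shock proteins with array medians set to 0 (-0.0826, where the median of all genes went from -0.02 to -0.18) and for ribosomal proteins with quantile normalization (0.0672) and without salinity replicate 2 (0.0291, the highest value with 1 array left out, where the lowest was -0.298). Os11g0454300 in mechanical stress was at -1.20 without mechanical replicate 2 and 4.53 without mechanical replicate 1.

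Counted over lists and alternatives, 114 of 136 values in mechanical stress against control, 171 of 204 in salinity against control and 122 of 153 in salinity against mechanical stress kept direction and side of the threshold. Over named genes these counts were 445 of 451, 830 of 1122 and 227 of 374. The first count does not show robustness, because 0 genes were called in that comparison and keeping the side of the threshold meant staying uncalled. Of the 1122 values, 273 lost and 19 gained the call, and of the 374, 143 lost and 4 gained it.

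Replicate numbers did not pair the arrays: differences between replicates 1 and 2 correlated across genes at 0.0243, 0.108 and -0.0655 between groups. With a replicate block, 0, 2680 and 250 genes were called, 2518 and 218 of them among the 5050 and 657. All arrays were on 1 slide, so a slide block was not run. Signal over background limits genes dim in a group, whose folds are bounds: 481 genes called higher in salinity were below background in control, and 116 called lower were below it in salinity.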

Other observations

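The tests of terms and of detection in this part were chosen only after the results were seen.

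Among genes that were in no gene list, those with the terms cytochrome P450, FAS1 domain and haem peroxidase were over-represented among the calls in salinity against control. Terms in the array's descriptions were tested for enrichment among the called genes against the 15233 tested genes with a description (166 terms, 664 tests, one-sided Fisher's exact test, adjusted over these tests). Fisher's test takes genes as independent, so its p-values may be too small where genes vary together. Camera with an estimated correlation called no list in salinity against control (lowest adjusted p = 0.208). Of 105 cytochrome P450 genes, 33 rose where 12.2 were expected (adjusted p = 2.95e-05), 7 fell, and the median log2 fold change was 0.78. Os02g0569900 was at least 61.2-fold higher, and Os03g0658800, chosen after its value was seen, rose by 5.16 ± 0.37. Of 18 genes with a FAS1 domain, found in cell surface arabinogalactan proteins, 9 fell where 1.46 were expected (adjusted p = 0.00119) and 1 rose. Chosen after their values were seen, Os04g0472200 had a log2 fold change of -3.90 ± 0.64 and Os08g0321000 one of -1.38 ± 0.22. Of 19 genes with the term haem peroxidase, 0 of them in the class III peroxidase list, 8 fell where 1.54 were expected (adjusted p = 0.0134). That list and this term were both caught by the wording of descriptions, so the 19 genes need not be a separate family. Between the stresses, 3 of 14 serine carboxypeptidase genes were lower in salinity (adjusted p = 0.0400).

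Some genes were above background on both arrays of 1 group and on no array of the others. They numbered 241 in salinity, of which 118 had a functional description (49.0%), 184 in mechanical stress, of which 24 had one (13%), and 67 in control, of which 17 had one (25.4%). Among all genes tested the share was 50.9%.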
